A study of Mus musculus with 12 samples.

How the data were processed

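Total RNA from the olfactory mucosa, the sheet of nasal tissue that holds the olfactory sensory neurons, was sequenced from 12 male mice at postnatal day 30, of mixed 129S6;C57BL/6J background. There were 6 wild-type animals and 6 animals with a large deletion on chromosome 7, and each animal gave 1 library. Libraries were ribodepleted and strand-specific, per the labels' protocols. The deletion runs from position 102509797 to 102918014 and spans 408217 bp, per the labels. The submitters' processing notes name STAR 2.6.0, DESeq2 and the genome build GRCm38.p6. The read counter is not given in the sources used here.

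The values analysed are per-gene signal values deposited by the authors, which are read counts divided by a size factor for each library. Each library's values are whole multiples of its smallest value above 0 (100% of values, tolerance 0.01 of a read), so whole reads and each library's depth were recovered. The deposited table also gives the authors' own comparison as a log2 fold change, which is wild-type over deletion and so has the opposite sign to the fold changes printed here. The same deposited table holds the authors' p-value and adjusted p-value for each gene, and a Wald score (fold change over its standard error) that was not used here. Values from the authors' comparison are printed only where they are named as such. The table as used here ends within a row: 39395 complete rows were used and 1 incomplete row was left out. The authors' adjusted p-values imply 42312 genes, so 2917 genes were not analysed here. The held rows with the highest adjusted p have authors' p-values from 0.913 upward.

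Recovered reads per library ranged from 10091239 to 18612011. Gene positions came from GENCODE release M21 on GRCm38, matched by Ensembl identifier for 39318 rows (99.8%). Odorant receptor genes were those with a symbol starting with Olfr. Class I receptor genes were the receptor genes on chromosome 7 between Rrm1 and Smpd1, and class II genes were all others. A gene was taken as deleted if it overlapped the deleted interval. Receptor genes form a large family of similar sequences, so counts of single members depend on how reads shared between copies were assigned.

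The test was limma 3.58.1 with a mean-variance trend and robust moderation (R 4.3.3), on log2 of the deposited value plus a pseudocount of 1, with group as the only term. Fold changes are therefore on the log2(value + 1) scale, which understates the change of genes with low counts. Genes were kept by the expression filter of edgeR 4.0.16 with a minimum count of 10, applied to the recovered reads, which left 17320 genes. P-values were two-sided and Benjamini-Hochberg adjusted over these genes, with a threshold of 0.05. The design written before the data were examined named edgeR's quasi-likelihood test for raw counts, and limma for size-factor-normalized values. Since the table holds the latter, limma gave the results and edgeR and DESeq2 1.42.0 on the recovered reads were run as alternatives.

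Values per animal were compared with exact permutation tests over all 924 assignments of 6 against 6, two-sided, for which the smallest possible p is 0.00216. Summed CPM (counts scaled to library size) used edgeR's TMM library sizes. Rank correlation with distance used 100000 permutations. Gene sets were tested with limma's camera with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The sets were both receptor classes and 26 lists of cell type markers and processes fixed before the data were examined. Where all deletion libraries had 0 reads, a fold is a lower bound against 3 counts over the 6 deletion libraries together, a mean normalized count of 0.494. Intervals and bounds cover counting error only.

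Genes named in the text followed a rule fixed in advance: the 5 deleted class I genes with the highest wild-type level; up to 8 lower and 4 higher class I genes outside the deletion and up to 4 class II genes in each direction by smallest p; the 2 tested class I genes nearest to the deletion on each side; up to 6 non-receptor genes in each direction with the largest change, at least 1 CPM, no overlap between groups and a named gene model; and up to 4 list members by smallest p. The rule was applied to the limma fit.

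The model was tested on simulated counts for the 17320 genes of the deletion and wild-type comparison, with 200 changed genes. It recovered 50 of 50 genes at a fold of 0.1, 50 of 50 at 0.25, 39 of 50 at 0.5 and 44 of 50 at 2, with 10 calls among the unchanged genes. Each gene was simulated independently, without structure shared between samples or added background reads. The changed genes were drawn from genes of all kinds. These rates therefore do not describe receptor genes in particular, or false calls from shared structure. Alternatives changed the test, the scaling, the filter, the pseudocount, the threshold, a replicate block and the libraries used. Added after the data were seen were edgeR with TMM, fits without the deletion libraries with many low-level reads, and subtraction of a background per kb of exon.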

Results

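The series compared the olfactory mucosa of 6 wild-type mice with that of 6 mice that carry a deletion of 408217 bp on chromosome 7 (GRCm38, 102509797 to 102918014). The labels describe it as the deletion of an enhancer of class I odorant receptors. These are the receptors encoded in a single cluster on that chromosome, while class II receptor genes lie in clusters elsewhere in the genome. The comparison asks how receptor genes that remain in the genome are expressed without this interval. Recovered reads per library ran from 13942401 to 18044908 in wild-type animals and from 10091239 to 18612011 in deletion animals. Of 17320 genes tested with limma, 9 were higher and 77 were lower in deletion animals (adjusted p under 0.05).

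Genes inside the deleted interval had almost no reads in deletion animals. All 19 tested class I genes there were lower, as were the other 2 tested genes, Trim21 and Trim68. The 30 listed genes in the interval held 10880 reads in wild-type libraries and 3 in deletion libraries (95% exact Poisson interval 0.619 to 8.77). Olfr549 (ENSMUSG00000073977.2, 102549870 to 102555842) had a mean normalized count of 192 ± 31.6 in wild-type animals (SD, n = 6) and 0 in all deletion animals, so it was at least 389-fold lower. The corresponding lower bounds were 310-fold for Olfr553, 241-fold for Olfr570 and Olfr569, and 232-fold for Olfr557. These values check the genotype labels of the 12 libraries.

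Class I receptor genes outside the deletion also fell. Of 120 listed there, 94 passed the expression filter and were tested. A further 13 annotated class I genes were among the genes not analysed here. Of 94 tested, 55 were lower, 1 was higher and 38 did not pass the test, and the median log2 fold change was -1.49. Adjusted over the list alone, 68 were lower and 6 higher. The ranges of the 2 genotypes did not overlap for 54 of the 94 genes (57.4%), against 0.216% by chance. Olfr585 (ENSMUSG00000078080.6, 103097720 to 103098749) dropped from 65.2 ± 10.1 to 2.17 ± 1.69 normalized counts (SD, n = 6; log2 fold change -4.50 ± 0.28 SE, limma adjusted p 3.99e-09). Olfr543 had a log2 fold change of -4.84, Olfr592 of -3.80, Olfr578 of -3.11 and Olfr629 of -3.11. Smaller losses were seen for Olfr642 (-2.64), Olfr67 (-2.09) and Olfr610 (-1.90). Against this direction, Olfr653 (ENSMUSG00000073926.4, 104577314 to 104584117) rose from 363 ± 47.6 to 858 ± 143 normalized counts (SD, n = 6; log2 fold change 1.23 ± 0.10 SE, limma adjusted p 4.57e-07), with every deletion animal above every wild-type animal. The median was -0.90 on the log2(CPM + 1) scale, where the pseudocount weighs more on genes with low counts.

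The loss was larger in the part of the cluster nearer to the deletion. Whether it changes gradually or in a step was not tested. The animals were of mixed background, so class I genes near the deletion can carry a linked segment of a parental strain. Whether such a segment contributes to the class I changes was not tested. The log2 fold change increased with distance from the deletion across the 94 genes (Spearman rho 0.62, Pearson r 0.61, permutation p = 1e-05, the smallest that 100000 permutations can give), and without the 2 genes farthest from the median distance rho was 0.61. Genes are not independent replicates. The 24 genes from Olfr543 to Olfr606 had a median of -2.43, with 22 lower, and the next 23, from Olfr607 to Olfr66, a median of -2.48, with 20 lower. Of the 23 genes from Olfr64 to Olfr658, 7 were lower and 1 was higher (median -0.44), and of the last 24, from Olfr659 to Olfr692, 6 were lower (median -0.30). Olfr545 and Olfr544, the nearest tested genes at lower coordinates, had log2 fold changes of -3.42 and -5.28. Olfr572 and Olfr575, the nearest at higher coordinates, had -1.85 and -2.05. The 3 genes at lower coordinates had a median of -4.84 and the 91 at higher coordinates -1.41, a difference that was not tested.

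**Figure D1:**
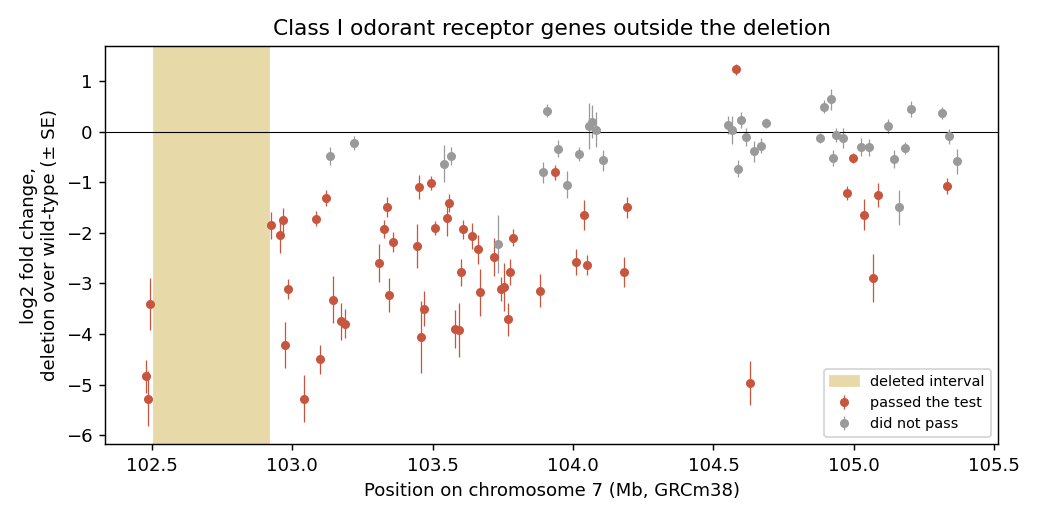
Log2 fold change (deletion over wild-type, log2(value + 1) scale, ± SE) of each of the 94 tested class I genes outside the deletion, against its position on chromosome 7 in Mb; colour shows whether the gene passed the limma test and the band is the deleted interval. Most points up to Olfr66 lie well below 0 (medians -2.43 and -2.48), and points farther along lie closer to it (medians -0.44 and -0.30).

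Summed over each animal, class I genes outside the deletion took 9.02% ± 1.33 of odorant receptor reads in wild-type and 5.20% ± 0.838 in deletion animals (SD, n = 6, exact permutation p = 0.00216, the smallest possible). With the deleted genes included, the wild-type share was 10.4% ± 1.49. Class I CPM outside the deletion fell from 592 ± 73.9 to 368 ± 59.4 (SD, n = 6, exact permutation p = 0.00216, adjusted over 3 sums 0.00649), and were lower in each deletion animal than in any wild-type animal. Class II receptors summed to 6018 ± 660 and 6740 ± 651 CPM (SD, n = 6, exact permutation p = 0.0887, adjusted 0.133), and all receptors to 6711 ± 664 and 7108 ± 660 (exact permutation p = 0.305, adjusted 0.305), so neither difference passed. The class II p was 0.0498 without wild-type replicate 2 and 0.0411 without deletion replicate 2, both from exact permutation tests and not adjusted.

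**Figure D2:**
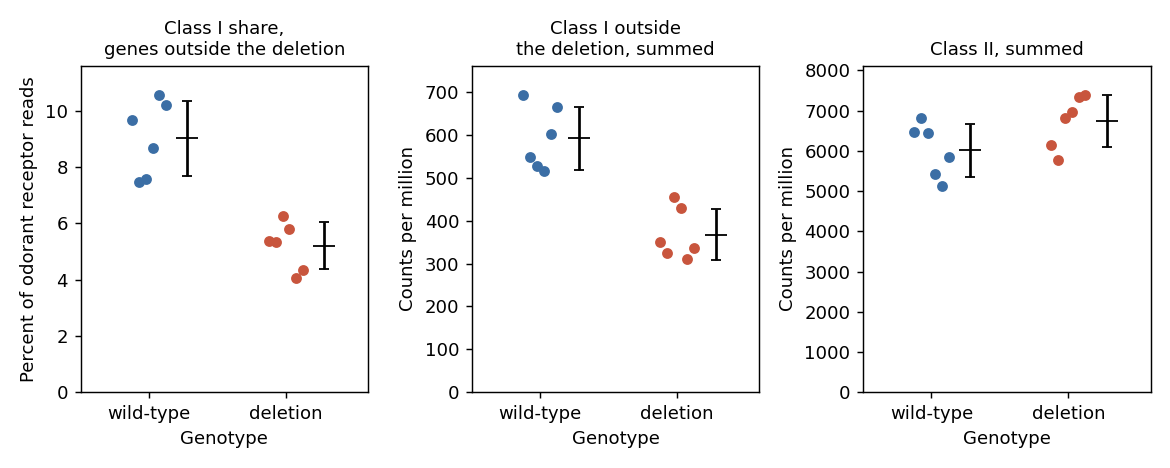
Class I share of odorant receptor reads over genes outside the deletion (percent), and summed CPM of class I genes outside the deletion and of class II genes; points are animals (6 per genotype) and bars are mean ± SD. The genotypes separate in the first 2 panels (9.02% against 5.20%, and 592 against 368) and overlap for class II (6018 against 6740).

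Among 859 tested class II genes, 1 was higher and 0 were lower by limma. The higher gene was Olfr221 on chromosome 14 (27.1 ± 5.80 against 53.2 ± 13.1 normalized counts, SD, n = 6; log2 fold change 0.94, limma adjusted p 0.0244). Adjusted over the list alone, 0 passed in either direction. At an unadjusted p under 0.05, 102 were higher and 0 lower, and 750 of the 859 had a positive fold change (87.3%, median 0.18). DESeq2 called 3 higher and edgeR with TMM called 2, and both called 0 lower. The number called was 0 without wild-type replicate 4, 5 or 6 or without deletion replicate 3, 4, 5 or 6, 2 without wild-type replicate 1, and 6 without deletion replicate 2. Of 13 tested vomeronasal and trace amine-associated receptor genes, 0 passed in limma, also at an unadjusted p under 0.05.

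Outside the receptor families and the deletion, 7 of 16333 genes were higher and 1 was lower. The 7 higher genes all lie on chromosome 18. Pcdhgb8, Pcdhb3, Pcdhb6 and Pcdhb7 belong to the clustered protocadherins, cell adhesion proteins of neurons, and had log2 fold changes of 1.31, 0.95, 0.90 and 0.55. They are the 4 that passed of 51 tested clustered protocadherins. Pcdhgb8 is annotated as a polymorphic pseudogene, and the others of the 4 as protein-coding. At an unadjusted limma p under 0.05, 11 of the 51 were higher and 3 lower. The sequences of these genes are similar, so reads shared between members leave single values uncertain. Greb1l rose from 105 ± 23.9 to 233 ± 59.4 normalized counts (SD, n = 6; log2 fold change 1.13, limma adjusted p 0.000573), and Riok3, an atypical protein kinase, from 1918 ± 54.9 to 2398 ± 237 (0.32, limma adjusted p 0.0172). Stard4 passed the test as well; its ranges overlapped, so it lies outside the naming rule and is named after its values were seen. Fam19a4 on chromosome 6, which encodes a secreted chemokine-like protein, fell from 80.2 ± 9.58 to 46.7 ± 7.64 (-0.77, limma adjusted p 0.00478). On chromosome 18, 48 of 424 genes (11.3%) had an unadjusted p under 0.05, against 514 of 15890 (3.23%) on other chromosomes. The lower count was 5 and the higher count 10 without deletion replicate 2, and the lower count was 2 without wild-type replicate 4 or deletion replicate 4.

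**Figure D3:**
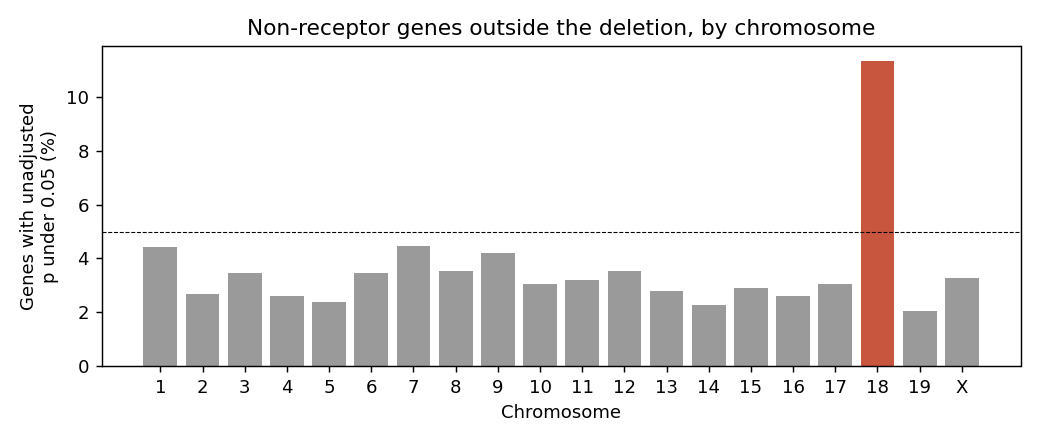
Percent of tested non-receptor genes outside the deletion with an unadjusted limma p under 0.05, by chromosome; the dashed line marks 5%. Chromosome 18 reaches 11.3%, and all other chromosomes together stand at 3.23%.

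Of 110 non-receptor genes within 5 Mb of the deletion, 0 passed in limma and 8 had an unadjusted p under 0.05 (7.27%, against 3.42% of other genes, Fisher's exact p = 0.0572). DESeq2 called 1. The number called was 3 without deletion replicate 2 and 1 without any of the 6 wild-type libraries, taken out singly.

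Markers of the cell types of the mucosa differed little. By camera with a preset correlation, 7 of 28 sets passed. Class I genes outside the deletion were lower (adjusted p 4.95e-104) and remained so with an estimated correlation (adjusted p = 0.00852). Class II genes passed as higher (adjusted p 3.23e-24) but not with an estimated correlation (adjusted p = 0.252). The immediate neuronal precursor and globose basal cell list, markers of the cells that renew the neurons, passed as higher (median log2 fold change 0.14, 11 of 13 members positive; adjusted p = 0.252 with an estimated correlation), with Neurod1 at 0.23 and Kit at 0.15. Proliferation genes (median 0.09, with Top2a at 0.15 and Cenpf at 0.15) and erythroid genes (median 0.30) also passed as higher, both with an adjusted p = 0.436 under an estimated correlation. The erythroid median was 0.10 without wild-type replicate 3 (adjusted p 0.187) and 0.46 without wild-type replicate 4, and that list did not pass without deletion replicate 6 either (0.18, adjusted p 0.0760). Proliferation genes did not pass without wild-type replicate 3 (adjusted p 0.204) or without deletion replicate 4 (0.0649) or 6 (0.103). Sustentacular cell markers, of the supporting cells of the epithelium, passed as lower (median -0.09, with Cyp1a2 at -0.21; adjusted p = 0.336 with an estimated correlation). This list did not pass by camera without deletion libraries 2 and 3 (-0.05, adjusted p 0.118) or without 2, 3, 4 and 5 (-0.06, adjusted p 0.153). Immune cell markers also passed as lower (median -0.12, with Cd74 at -0.25; adjusted p = 0.436 with an estimated correlation). The immune list did not pass without wild-type replicate 4 or 6 or without deletion replicate 1, 2, 4 or 6, each taken out singly (adjusted p 0.0560 to 0.156). No member of these 5 marker lists passed the test over all genes or adjusted over the list alone. The remaining 21 sets had adjusted p-values of 0.0513 to 0.963, but 12 of them passed under some of 27 alternatives, none with an estimated correlation. Neutrophil and marrow genes (median -0.28, adjusted p 0.0513) passed as lower in 13, among them the fits without wild-type replicate 3, 5 or 6 or deletion replicate 2 or 5 (adjusted p 0.00910 to 0.0435). Trace amine-associated receptors (median 0.12) passed as higher in 9, among them those without wild-type replicate 2, 5 or 6 or deletion replicate 2, 3 or 5 (0.00174 to 0.0316). The median of these receptors was 0.01 without wild-type replicate 4. Endothelial markers (median -0.13) passed as lower in 8, among them those without wild-type replicate 4 or deletion replicate 1, 2 or 5 (0.00226 to 0.0469). The endothelial median was -0.01 without deletion replicate 6. Immature neuron markers (median 0.04) passed as higher in 6, among them those without wild-type replicate 4 or deletion replicate 1 or 3 (0.0193 to 0.0404). The other 8 passed in 1 to 3, among them, with single libraries left out, Bowman's gland (0.0435 without wild-type replicate 2), mature neuron (0.0413 without wild-type replicate 6), horizontal basal cell (0.0148) and bone and fibroblast markers (0.0301, both without deletion replicate 5). In the fit with all libraries, mature olfactory sensory neuron markers had a median of -0.03, with 0 of 18 members passing. In the immature neuron list, Dpysl3, a gene of chromosome 18 that acts in axon growth, passed when adjusted over the list alone (log2 fold change 0.27, adjusted p 0.00567) but not over all genes (limma adjusted p 0.0694).

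Libraries differed in how many genes had any read. In wild-type libraries 65.2% to 69.3% of listed genes had at least 1 read. Deletion replicate 3 reached 94.6%, replicate 2 80.6%, replicate 5 75.6% and replicate 4 73.1%, while replicates 1 and 6 had 67.2% and 67.4% (67.5% ± 1.504 against 76.4% ± 10.25, SD, n = 6, exact permutation p = 0.0368). Over 96 genes of 4 families with few reads in wild-type libraries (Defa, Defb, Krtap and Tas2r), deletion replicate 3 had 3.44 reads per kb of exon, against 0.533 to 0.793 in wild-type libraries. Defb was the least silent, with a mean of 2.25 reads per kb in wild-type libraries and 5.84 in deletion replicate 3. Krtap had 0.0584 and 2.80. These rates are not scaled to library depth. Without deletion replicates 2 and 3, limma called 23 genes higher in total, 9 class II genes higher, 13 non-receptor genes higher and 10 lower, and 6 genes within 5 Mb of the deletion.

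**Figure D4:**
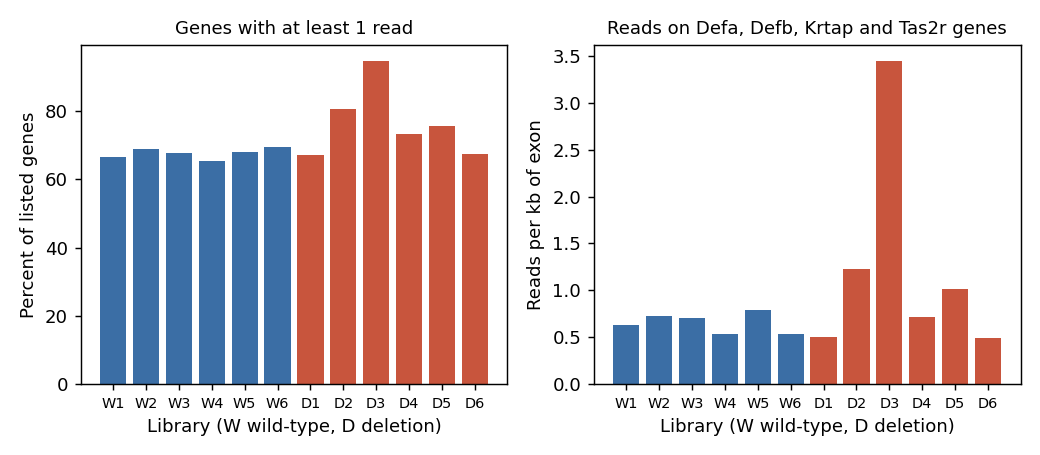
Percent of listed genes with at least 1 read, and reads per kb of exon over 96 genes of the same 4 families, in each of the 12 libraries (bars, 1 value per library). Deletion replicate 3 stands highest in both panels, at 94.6% and 3.44 reads per kb.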

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

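Tests on the chromosome 18 share outside protocadherins and among uncalled genes, on a chromosome's share relative to the others in splits of the animals, on reads inside the deletion in deletion replicate 3, and of neuron scaling and background for the class II median were chosen after the results were seen. The other tests were written down first.

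Single animals stood apart from their group in 6 of 69 sets of 6 values, where chance gives about 3.45. Olfr578 was at 145 normalized counts in wild-type replicate 1, against 89.1 to 108 in the others. In deletion replicate 3, Olfr585 was at 5.49 (others 0.843 to 2.05), Olfr592 at 37.1 (others 7.52 to 15.7) and Olfr545 at 9.61 (others 0 to 3.37). Fam19a4 was at 61.2 in deletion replicate 6, against 41.0 to 48.1. The share of reads on genes too low to test was 0.915% in deletion replicate 3, against 0.180% to 0.349% in the other deletion animals. That share also lay above the highest wild-type library (0.247%) in deletion replicate 2 (0.349%) and deletion replicate 5 (0.255%).

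The excess low-level reads of deletion replicate 3 were set against 3 sources. RNA or DNA of wild-type animals would bring reads inside the deletion: the rate over the Defa, Defb, Krtap and Tas2r families gives 274 expected reads there, and 1 was found. RNA of another tissue would favour some of these families, but the highest and lowest rates lay within 2.44 times of each other (2.08 without Defa, which rests on 1 read). The highest was that of Defb, which had reads in wild-type libraries as well. Of autosomal protein-coding genes nearly silent in wild-type libraries, 95.0% had a read. Genomic DNA of the same male animal predicts an X-to-autosome ratio of 0.5 in reads per kb over such genes. The measured ratio was 0.673 (bootstrap interval 0.582 to 0.769), so the prediction of 0.5 was missed. That interval covers the draw of genes only. The ratio also lies below 1, and the ratio of median rates, examined afterwards, was 0.535. These measures disagree, so whether this DNA is the whole source is not decided. A mixture of sources stays open and was not tested, and no biological explanation was tested.

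The cluster of changed genes on chromosome 18 holds called genes from position 10325177 to 37841870. Reads shared between protocadherin paralogs cannot account for the other genes, of which 34 of 371 had a p under 0.05 (9.16%, against 3.23% elsewhere, Fisher's exact p = 1.27e-07). For the protocadherins themselves it stays open: their summed CPM were 753 ± 43.4 and 783 ± 31.2 (SD, n = 6, exact permutation p = 0.195), and a p above the threshold does not show equality. A segment from the other parental strain, shared by many deletion animals, is a candidate explanation. Genes that were not called were also enriched (41 of 417, 9.83%, Fisher's exact p = 1.03e-09). Any cause acting along this chromosome could give that, so it does not favour a segment. With called genes included, the share up to 20 Mb was 21.8% of 55 genes, and 11.4% of 176 from there to 40 Mb. It was 12.5% of 64 genes at 40 to 60 Mb, 6.93% of 101 at 60 to 80 Mb and 3.57% of 28 beyond. This unevenness was not tested, so it does not settle whether the cause is local. Of all 48 such genes on chromosome 18, 29 were higher and 19 lower. Some chromosome had a share as high in 18 of 100 splits of the 12 animals (11.3% in the real grouping, highest other 26.5%), but that share also rises in splits that raise all chromosomes. Taken relative to the other chromosomes, the ratio of shares was as high in 1 split, the real one (3.497, highest other 3.455), and the difference in percentage points in 6 (8.08, highest other 12.7), so these measures disagree on whether chance is excluded, and an effect of the deletion itself remains untested.

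The third pattern is the positive median log2 fold change of class II genes (0.184), which as a set did not pass with an estimated correlation (adjusted p = 0.252). Against the wild-type mean, the medians of deletion replicates 1, 2 and 3 (0.08, -0.04 and 0.16) lay within the range of wild-type animals (-0.15 to 0.18) and those of replicates 4, 5 and 6 (0.29, 0.31 and 0.34) above it. If a difference in neuron content were the cause, scaling by mature neuron markers would lower the median, but it rose to 0.236. That shift is small beside the SD of 0.151 between deletion animals' medians, so it argues against this cause only weakly. Background reads stay open: subtracting them lowered the median to 0.119, while without deletion libraries 2 to 5 it was 0.215. Of 100 splits of the animals, 8 gave a median as large (highest other 0.256), so chance is not excluded. The medians also followed a split of the animals other than genotype, described below as the split with 197 calls. Wild-type replicates 1 and 2 and deletion replicates 3 to 6 ran from 0.09 to 0.34, and all others from -0.15 to 0.08. That split was picked for having the most calls among those drawn, and 18 of its 197 calls were class II genes. The medians are therefore no independent evidence of it. A structure of the samples other than genotype stays open as well. Choice of class II genes by neurons that would otherwise express class I is a hypothesis for an effect of the genotype, and it was not tested.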

How the results depend on the processing

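Of the values that answer a comparison, 468 stayed on the same side or within 1.5 times, 62 moved, 2 became significant and none reversed, but some counts reached 0 (class II higher, sets higher). The loss of class I genes outside the deletion held in each alternative, with 50 to 60 lower, as did the correlation with distance (rho 0.50 without a filter, up to 0.62). The causes of the changes below were not tested. With single libraries left out, genes higher ranged from 6 to 17, class I higher from 1 to 2, class II higher from 0 to 6, non-receptor lower from 1 to 5, genes near the deletion from 0 to 3, sets higher from 2 to 6, sets lower from 2 to 7, and the class II log2 ratio of summed counts from 0.12 to 0.20.

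DESeq2 gave 15 genes higher, 3 class II higher, 11 non-receptor higher and 3 lower, and 1 near the deletion. edgeR gave 2 class II higher and 2 sets higher with median-of-ratios factors, and the same counts, 2 and 2, with TMM. Without a filter, 16 genes were higher, 2 class I higher, 13 non-receptor higher and 2 lower, 2 near the deletion, 1 set higher and 11 lower, and the class I median was -1.06, since more low genes entered. On log2(CPM + 1) that median was -0.90. Scaling by neuron markers gave 5 sets lower. At a threshold of 0.01, 5 genes were higher. Camera with an estimated correlation left 0 sets higher and 1 lower; fry gave class I an adjusted p of 0.000194 and every other set at least 0.279. The replicate number used as a block gave 5 genes higher, 0 class II higher, 4 non-receptor higher and 4 on chromosome 18. The numbers do not pair the samples: same-number correlations ran from -0.243 to -0.00728, and no sample correlated best with its own number.

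Chosen after seeing the data, leaving out deletion libraries 2 and 3 gave 23 genes higher, 9 class II higher, 13 non-receptor higher and 10 lower, 6 near the deletion and 1 set lower. Leaving out deletion libraries 2, 3, 4 and 5 gave 2 class II higher, 5 non-receptor lower, 5 near the deletion, 1 on chromosome 18 and 6 sets lower, with fewer samples. Subtracting background gave 7 sets higher. Shares and sums of reads have no value of their own under DESeq2, edgeR with TMM, log2(CPM + 1) or no filter. In simulation with independent genes at the depth of these libraries, 39 of 50 genes were recovered at a fold of 0.5. Other depths and structure shared between samples were not simulated.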

Other observations

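The genes in this paragraph, apart from Olfr653 and Olfr642, were chosen after their values were seen. Olfr657 (104624794 to 104637481) had 51.1 ± 11.7 normalized counts in wild-type and 1.23 ± 2.22 in deletion animals (SD, n = 6; log2 fold change -4.97, limma adjusted p 4.87e-07). The genes on either side of it, Olfr656 and Olfr658, had log2 fold changes of -0.10 and -0.39 and did not pass (limma adjusted p 0.955 for both). Olfr653, the class I gene that rose, starts at 104577314 in the same stretch. Around it, Olfr651, Olfr652 and Olfr655 did not pass either (log2 fold changes 0.14, 0.04 and 0.23). Olfr654 did not pass over all genes (-0.73, limma adjusted p 0.0766), but its ranges in the genotypes did not overlap. Some other losses far along the cluster came in adjacent tested genes: Olfr641 (-1.65) fell with Olfr642 (-2.64), Olfr648 (-2.78) with Olfr649 (-1.49), Olfr671 (-1.22) with Olfr672 (-0.52) and Olfr678 (-2.89) with Olfr679 (-1.25). Others fell between tested genes that did not pass: Olfr632 (-0.80), Olfr639 (-2.58), Olfr690 (-1.08) and Olfr676 (-1.64), the last between Olfr675 and Olfr677 at -0.30 and -0.31.

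The test of the relation with distance was written before its result was seen. A hypothesis for the larger loss of class I genes nearer to the deletion is that near and far genes differ in their wild-type level. That level could set the size of a fold change on the log2(value + 1) scale. Given the wild-type mean, the partial Spearman rho of log2 fold change with distance was 0.615 across the 94 genes (permutation p = 1e-05, the smallest possible), beside 0.618 without that adjustment, which argues against level as the cause. The correlation of fold change with wild-type level itself was 0.19. Genes are not independent replicates.

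Other splits of the 12 animals into 6 and 6 were drawn 100 times, the real grouping included. For class I genes outside the deletion, 1 split, the real one, gave as many calls (56, highest other 0). This is the smallest share that 100 draws can give, and it argues against a chance split for that count. Likewise 1 split did for genes inside the deletion (21, highest other 0). There the missing sequence sets the values by genotype, so the splits add nothing. For all genes 2 splits gave as many (86, highest other 197), for non-receptor genes 2 (8, highest other 179) and for class II genes 2 (1, highest other 18). The share of splits is under 0.05 for these 3 counts, but each has another split with more calls. The class II count rests on Olfr221 alone, and 7 of the 8 non-receptor genes lie on chromosome 18. For gene sets with a preset correlation, 31 splits gave as many (7, highest other 13), so chance is not excluded for that count. The split with 197 calls set wild-type replicates 1 and 2 with deletion replicates 3 to 6 against the rest. It was picked for its number of calls, so a structure of the samples other than genotype stays open and is not shown. In a principal component analysis of all 17320 tested genes, the first component (24.5% of the variance) separated the genotypes. These genes include the deleted genes and the class I genes that fell, so the separation may come from them. Over the 16333 non-receptor genes alone the first component (18.9%) did not separate the genotypes.

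In the authors' deposited table, 100 genes had an adjusted p under 0.05, of which 85 were higher in wild-type and 15 higher in deletion animals. Of the 86 genes called by limma, 85 were among them, including 55 class I genes outside the deletion.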
